A study of Mus musculus with 6 samples.

How the data were processed

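The series measured polyadenylated RNA of blood monocytes from mice in 6 libraries, 3 labelled thrombocytopenic (genotype PF4cre-iDTR) and 3 labelled control (wild type), with diphtheria toxin named as treatment in both. Groups, replicate numbers and the name of the cells come from the labels. Per the labels' protocols, RNA was purified with oligo-dT beads, libraries were prepared with a stranded TruSeq kit that marks the second strand with dUTP, and sequencing was done on a NovaSeq instrument. Per the submitters' processing notes, fastp 0.23.1, STAR 2.7.9a, Subread 2.0.1 with featureCounts and Salmon 1.5.2 were used; the role and order of these tools, the genome build, the annotation and the counting settings are not given in the sources used here. The deposited values are raw counts per gene, whole numbers with a different total in every file, in 1 file per library with the same 56832 gene names. No row stood for unassigned reads. Gene symbols are used as in the files, and no coordinates are printed because the build is not given. Whether the counting used strand is not given either, so overlapping and antisense genes, near copies and gene families are uncertain.

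The counts were analysed as deposited with R 4.3.3. Of the 56832 genes, 34221 had no count in any library and 12488 passed edgeR's filterByExpr (minimum count 10, minimum total count 15). TMM factors ranged from 0.9943 to 1.002. The groups were compared with edgeR 4.0.16 (quasi-likelihood test, robust fit, group as the only term, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic of that test. CPM values of single genes are scaled by the TMM factors and given as mean ± SD over 3 libraries; sums over marker lists are CPM on the library totals. For genes with 3 or fewer counts in a group the summed counts are given, with a 95% counting interval of the ratio, or a bound against a floor of 3 counts over the group where a group had 0; these cover counting error only, since PCR copies are not independent molecules. The 24842319 to 37552029 counts per library leave genes under about 1 CPM with few counts.

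The 34 gene lists, the rule for named genes and the tests of genes, lists and sums in the main comparison were fixed before the data were examined. The lists added for the closing part, some of its tests and 1 alternative were chosen afterwards. The lists hold markers of platelets, monocytes and their subsets, neutrophils, B cells, T and NK cells, erythroid, dendritic, progenitor, and basophil, eosinophil and mast cells. They also hold genes of cytokines, Toll-like receptor and NF-kB signalling, type I and gamma interferon responses, MHC class I and II presentation, phagocytosis, and platelet contact. Metabolic and other lists cover glycolysis, hypoxia, oxidative phosphorylation, the citrate cycle, fatty acid oxidation, cholesterol biosynthesis, iron and haem recycling, histone methylation, cell cycle, ribosomal proteins, mitochondrially encoded, immediate early, sex-linked and substrain genes, and the chromosomal neighbours of Pf4. Some genes are in more than 1 list. Lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. fry was run beside it; it tests whether the genes of a list move, on balance, in 1 direction and compares them with no other genes. Summed CPM of marker lists were compared by an exact permutation test, two-sided, whose smallest p with 3 against 3 libraries is 0.1.

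Named genes are the 12 higher and 12 lower genes with the smallest p and the 4 higher and 4 lower genes with the largest fold change, all with an adjusted p under 0.05, a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a predicted gene, clone or pseudogene name. To these were added up to 4 tested members of each list with the smallest p, and 30 genes always considered. Some genes that meet this rule are not reported here. Other genes that appear in the text were chosen after their values were seen and are marked as such or are exceptions within a list.

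The steps were tested on simulated data, with counts for the 12488 genes drawn from the means and library sizes of the thrombocytopenic against control comparison. The test recovered 58% of genes changed by 1.25-fold, 76% at 1.5-fold, 92% at 2-fold and 98% at 4-fold. It called 16 of 12266 unchanged genes, 8.04% of all calls, above the share of 0.05 that the threshold aims at. The shifted list was the 1 list called of 33. Genes were drawn independently, so this list result does not cover lists of correlated genes. Far fewer genes were changed in the simulation than in the data. Alternatives were RLE, upper quartile and library total scaling, DESeq2 1.42.0, limma-voom, edgeR without the robust option, other filters and thresholds, a replicate block, removal of marker and mitochondrial genes, and leaving out each library in turn. For gene length and GC content, names were matched to GENCODE M21, which held 50610 of them.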

Results

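RNA sequencing profiled cells that the labels name as monocytes from the peripheral blood of mice, in 2 groups. Their state was not compared with that of circulating monocytes, and abundant macrophage genes among their RNA are given in the closing part. The thrombocytopenic group (3 libraries) had the genotype PF4cre-iDTR, in which Cre recombinase under control of the promoter of Pf4 (platelet factor 4), active in megakaryocytes, switches on a receptor for diphtheria toxin. Whether that promoter was also active in the profiled cells was not tested. The control group (3 libraries) was wild type. The labels list diphtheria toxin as the treatment of both groups, so the groups differed in genotype as well as in platelet state, and these cannot be told apart here. The comparison asks how monocyte RNA differed between mice with and without thrombocytopenia. The files summed to 37552029, 29883019 and 35730418 counts in the thrombocytopenic libraries and to 24842319, 35955383 and 28654146 in the control libraries. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Libraries of a group correlated at 0.9951 to 0.9964 (Pearson, log2 CPM, across genes, which are not independent replicates), and libraries of different groups at 0.9855 to 0.9867. Every pair within a group differed by more than sampling noise, with a chi-square statistic of 1.91 to 3.27 per degree of freedom, and no library was counted as a copy of another.

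Monocytes of thrombocytopenic mice carried more RNA for sterol synthesis genes and less for the cholesterol exporter Abcg1 and for Apoe. Il1b, Ptgs2 and Il6 were higher, while the chemokine genes Ccl2 and Ccl7 and the nitric oxide synthase gene Nos2 were lower. Interferon response, MHC class II and cell cycle genes were lower as groups by camera with its preset correlation. With an estimated correlation the cell cycle list held (adjusted p = 0.0484), while the 2 interferon lists (0.0805 each) and MHC class II (0.187) did not. Several platelet and basophil transcripts were nearly missing from the thrombocytopenic libraries, while Pf4 itself was higher there. Most of these were low in the control libraries too, and the platelet genes Tubb1 and Gp6 were near the floor in both groups. Of 12488 genes tested, 5626 (45.1%) changed, 2792 higher and 2834 lower in the thrombocytopenic group, by edgeR's quasi-likelihood test at an adjusted p under 0.05. Most changes were small: 4423 of these genes changed by under 1.5-fold. At least 2-fold changes numbered 489, of which 112 were higher and 377 lower, and at least 4-fold changes numbered 10 higher and 82 lower. The 3 thrombocytopenic libraries lay wholly above or below the 3 control libraries for 6404 genes (51.3%), against 10% by chance. The first principal component held 67% of the variance and separated the groups. The common biological coefficient of variation was 2.68%, so that small differences passed the test. This low value describes these libraries, and the labels do not say whether it includes any variation between animals.

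Of 34 gene lists fixed before the data were examined, 33 had at least 3 tested members, and 12 differed from the other genes by camera with its preset correlation of 0.01, 4 higher and 8 lower. With an estimated correlation 3 of them held: cholesterol biosynthesis, cell cycle and the chromosomal neighbours of Pf4. Other splits of the same 6 libraries, which mix both groups in each arm, gave up to 10 lists with the preset correlation. Adjusted over the list alone, the counts of higher and lower members equalled those over all genes in 25 lists; the other 9 are given with their lists. Members named as exceptions within a list were chosen after their values were seen.

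**Figure D1:**
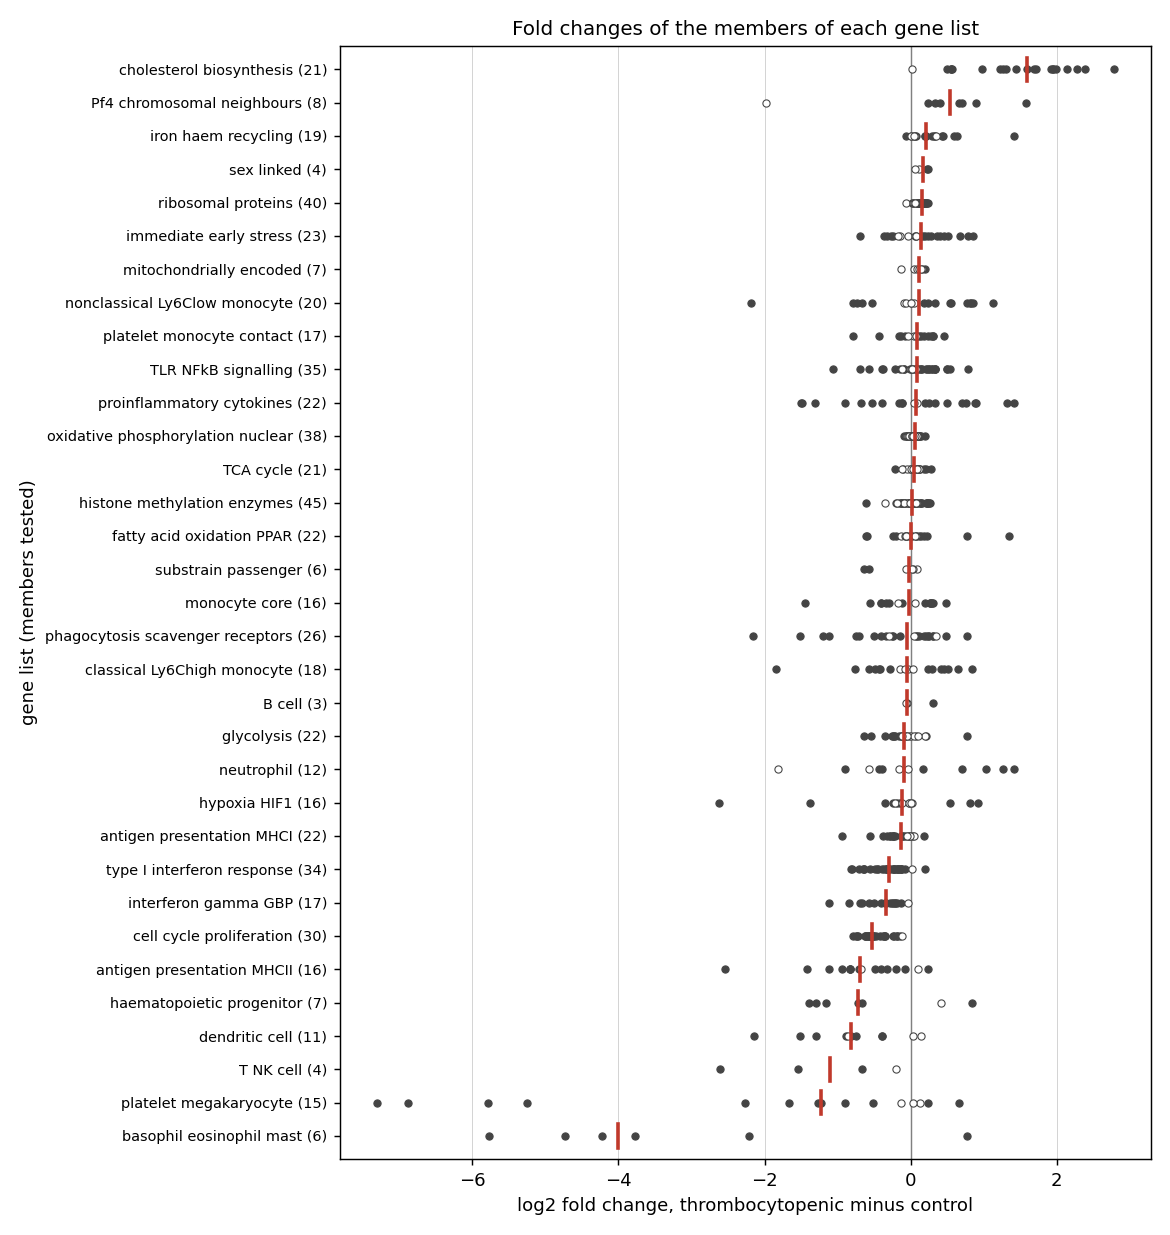
Log2 fold changes (x axis, thrombocytopenic minus control, 3 libraries a group) of the tested members of each list with at least 3 of them (y axis, number tested in brackets), filled where the adjusted p was under 0.05 and open elsewhere, with the list's median as a red bar; the value of Gp9, at 0 counts in the thrombocytopenic group, is a fitted one. Cholesterol biosynthesis had the highest median (1.60) and the basophil, eosinophil and mast cell list the lowest (-4.00).

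Genes of the cholesterol biosynthesis list rose together: 20 of 21 tested members were higher, 15 of them at least 2-fold. None was lower, and the median log2 fold change was 1.60. Camera gave an adjusted p of 3.87e-83, and adjusted p = 0.00319 with an estimated correlation. Sqle, squalene epoxidase, rose from 7.32 ± 0.070 to 50.3 ± 1.35 CPM (mean ± SD, n = 3 in each group; log2 fold change 2.78, SE 0.060). Cyp51, a sterol demethylase, rose from 17.6 ± 0.814 to 85.9 ± 1.98 CPM (2.28, SE 0.046). Hmgcs1 rose by 1.72 (SE 0.034) on the log2 scale. Msmo1 rose by 2.14, Stard4, a sterol transfer protein, by 2.61, and Srebf2, the transcription factor that drives these genes, by 1.27. Ebp did not pass the test, at 32.0 CPM against 31.5 CPM. Lpl, lipoprotein lipase, rose from 1284 ± 30.1 to 3270 ± 65.8 CPM (log2 fold change 1.35). The opposite change was seen in Abcg1, a cholesterol exporter, which was 18.1-fold lower at 7.20 ± 0.511 CPM against 130 ± 4.55 CPM (log2 fold change -4.18, SE 0.051; edgeR adjusted p = 1.24e-51). Apoe, apolipoprotein E, fell from 1011 ± 39.7 to 369 ± 4.13 CPM (-1.45, SE 0.027). The small GTPase gene Arl4c had a log2 fold change of -3.15. Abca1, another cholesterol exporter and chosen after its values were seen, was at 188 ± 11.8 CPM against 836 ± 48.9 CPM (-2.16, SE 0.064). The mitochondrial ribosomal RNA mt-Rnr2 was lower too, at 165 ± 4.52 CPM against 1018 ± 48.8 CPM.

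**Figure D2:**
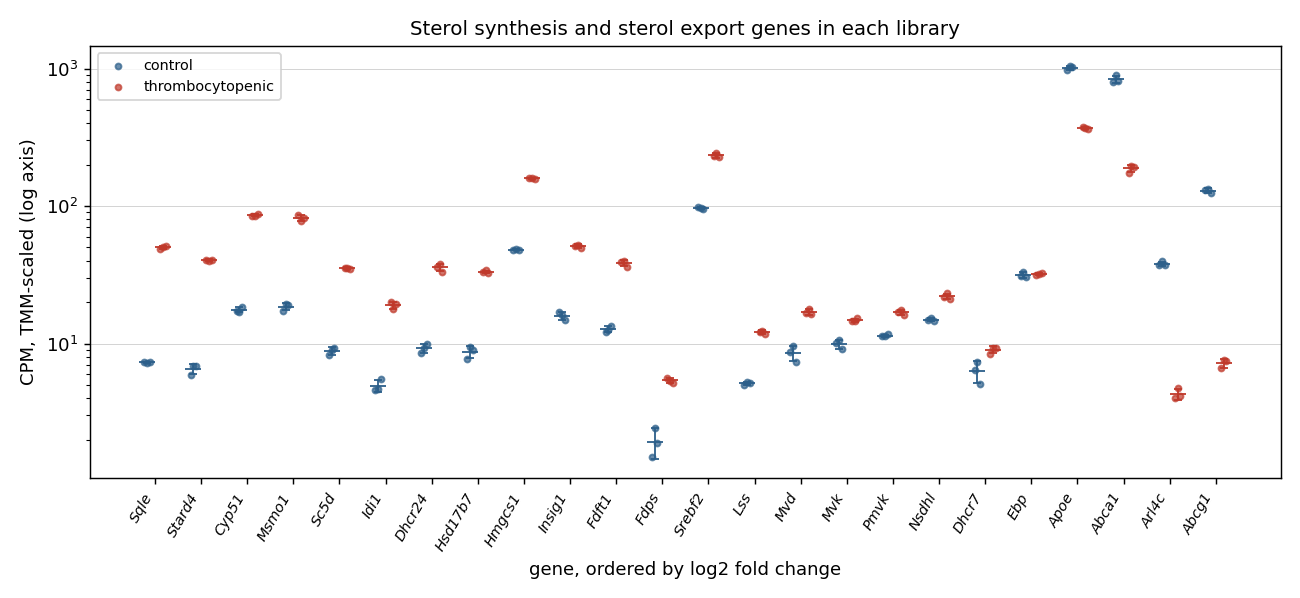
Normalised read count (CPM, log axis) of cholesterol biosynthesis genes and of Stard4, Abca1, Abcg1, Apoe and Arl4c (added after their values were seen) in each of the 3 control (blue) and 3 thrombocytopenic (red) libraries, with the mean and SD as bars. The thrombocytopenic libraries lay above the control libraries for every list member drawn except Ebp, and below them for Abca1, Abcg1, Apoe and Arl4c.

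Genes of proinflammatory cytokines, chemokines and related enzymes changed in both directions, with 10 of 22 tested members higher, 10 lower and 2 not past the threshold (Il12a and Il18). The list did not differ from other genes (camera adjusted p = 0.691). Il1b, the gene of interleukin 1 beta, rose from 462 ± 4.94 to 1156 ± 52.2 CPM (log2 fold change 1.32, SE 0.027). Il6 rose from 54.4 ± 1.19 to 99.7 ± 3.29 CPM (0.88, SE 0.037). Ptgs2, cyclooxygenase 2, chosen after its values were seen, rose by 1.41 on the log2 scale. Tnf rose by 0.25 (SE 0.024), from 1122 ± 15 to 1331 ± 28.1 CPM. The monocyte chemoattractant gene Ccl2 fell from 911 ± 8.68 to 321 ± 15.3 CPM (log2 fold change -1.51, SE 0.028). Ccl7, another chemokine gene, fell from 788 ± 12.7 to 281 ± 6.85 CPM (-1.49, SE 0.026). Nos2 fell from 434 ± 8.01 to 175 ± 6.83 CPM (-1.31, SE 0.029). Cxcl10 fell from 5030 ± 161 to 3477 ± 118 CPM (-0.53). Serpinb2, the gene of plasminogen activator inhibitor 2, was 5.75-fold higher, and Samsn1, an adaptor gene of blood cells, 2.35-fold higher. Among Toll-like receptor and NF-kB genes 18 of 35 were higher and 9 lower (19 and 9 adjusted over the list alone; camera adjusted p = 0.0549). The list was called higher without thrombocytopenic replicate 3 (adjusted p = 0.03) and without a filter on low counts (0.0109). Nfkbiz rose by 0.78 and Rel by 0.54. Tlr2 had a log2 fold change of -0.69 and Tlr9 of -1.06. Tlr4, the lipopolysaccharide receptor, was at 20.6 ± 1.75 CPM against 22.2 ± 2.12 CPM and did not pass the test (log2 fold change -0.12), but did without control replicate 1 (-0.18, adjusted p = 0.02). Its co-receptor gene Cd14 rose by 0.29 on the log2 scale. Summed neutrophil markers stood at 297 ± 6.59 CPM against 238 ± 5.40 CPM in the same libraries (exact permutation p = 0.1, the smallest possible), while their mean log2 CPM differed by -0.254, in the opposite direction.

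**Figure D3:**
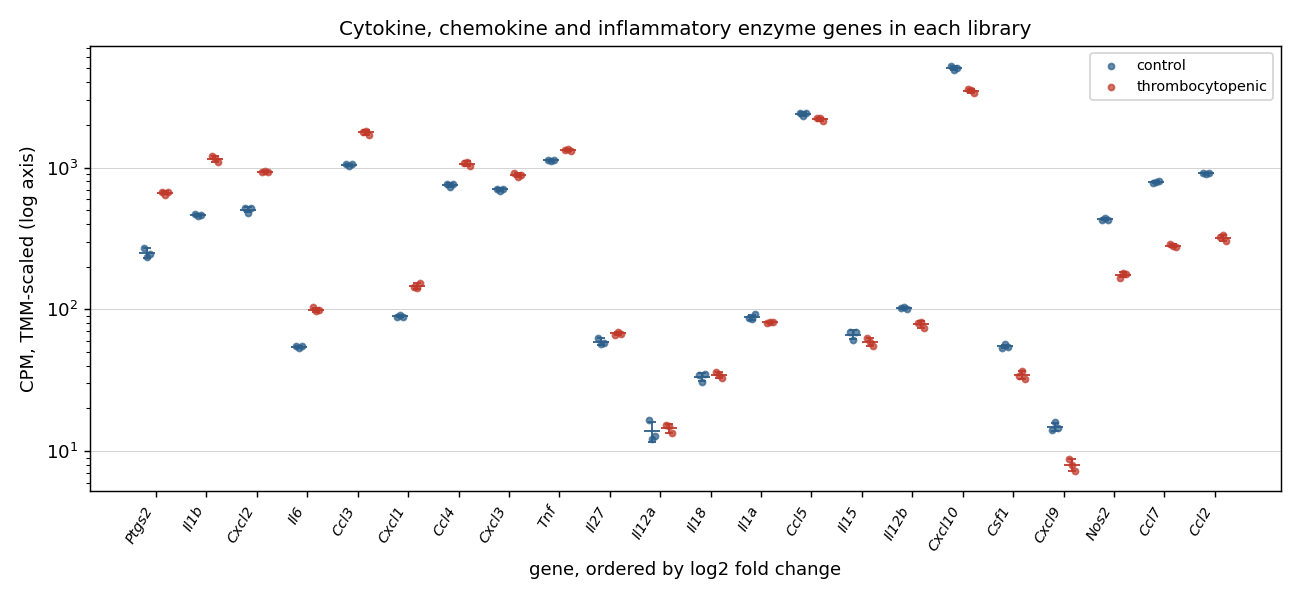
Normalised read count (CPM, log axis) of the 22 tested members of the proinflammatory cytokine list in each of the 3 control (blue) and 3 thrombocytopenic (red) libraries, ordered by fold change, with the mean and SD as bars. Ptgs2 and Il1b stand at the higher end and Ccl7 and Ccl2 at the lower end.

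Type I interferon response genes were lower as a group: 32 of 34 tested members were lower, Ifi27l2a was higher (0.20) and Irf9 did not pass the test (log2 fold change 0.02). The median was -0.30, and camera gave an adjusted p of 2.64e-18, with adjusted p = 0.0805 with an estimated correlation. The antiviral gene Rsad2 fell from 6890 ± 90.3 to 3913 ± 32.7 CPM (log2 fold change -0.82, SE 0.022). Ifit2 fell from 1551 ± 27.2 to 890 ± 13.1 CPM (-0.80, SE 0.024), and Cmpk2 had a log2 fold change of -0.64. Ifit3, which shares reads with its near copy Ifit3b and is uncertain for that reason, had a log2 fold change of -0.64. Of the guanylate-binding protein and related interferon gamma genes 16 of 17 were lower, with a median of -0.34 (camera adjusted p = 4.9e-08; adjusted p = 0.0805 with an estimated correlation). Irgm2 did not pass the test (-0.03). Iigp1 was at -0.84, Gbp9 at -0.66 and Gbp3 at -0.56. MHC class II presentation genes were lower in 13 of 16 members and higher in 1, Cd80. Their median was -0.70 (camera adjusted p = 5e-06; adjusted p = 0.187 with an estimated correlation; 14 lower adjusted over the list alone). H2-Ab1 fell from 77.1 ± 2.44 to 43.1 ± 3.38 CPM (log2 fold change -0.83, SE 0.043). Cd74, the invariant chain gene, fell from 247 ± 5.72 to 151 ± 12 CPM. The co-stimulatory gene Cd86 was at -0.93 and the class II transactivator gene Ciita at -1.12 on the log2 scale. For MHC class I, 14 of 22 were lower and 1, the proteasome activator gene Psme2, was higher. Their median was -0.13 (camera adjusted p = 0.0265; adjusted p = 0.266 with an estimated correlation). Tap1 was at -0.28 and H2-T22, one of a family of similar genes, at -0.38. Dendritic cell markers moved the same way in these libraries, 8 of 11 lower and none higher. Their median was -0.82 (camera adjusted p = 0.00994; adjusted p = 0.148 with an estimated correlation). Among them Ccr7 was at 15.2 ± 1.34 CPM against 28.0 ± 1.83 CPM and Siglech at 0.313 ± 0.064 CPM against 1.39 ± 0.099 CPM.

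Cell cycle genes were lower: 29 of 30 fell, none rose and Mcm2 did not pass the test (log2 fold change -0.12). The median was -0.52 (camera adjusted p = 2.97e-11; adjusted p = 0.0484 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell from 187 ± 1.63 to 128 ± 3.41 CPM (log2 fold change -0.55, SE 0.030). Bub1b was at -0.79, Ccna2 at -0.62 and Mcm6 at -0.47. Markers of blood progenitors were lower in the same libraries in 5 of 7 members, and Meis1 was higher (camera adjusted p = 0.271 for the list; 2 higher and 5 lower adjusted over the list alone). Kit was at 1.27 ± 0.433 CPM against 2.84 ± 0.487 CPM and Flt3 at 0.695 ± 0.166 CPM against 1.71 ± 0.226 CPM. Ribosomal protein genes were slightly higher, 35 of 40 with none lower and a median of 0.15 (camera adjusted p = 0.000203; adjusted p = 0.425 with an estimated correlation). Rps27a was at 0.24 and Rpl4 at 0.16.

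Iron and haem recycling genes were higher in 12 of 19 members and lower in 1, Fth1. Their median was 0.21 (camera adjusted p = 3.69e-05; adjusted p = 0.0805 with an estimated correlation). The cystine transporter gene Slc7a11 rose from 1310 ± 13.4 to 2028 ± 85.8 CPM and the iron exporter gene Slc40a1 from 3.64 ± 0.099 to 9.72 ± 0.994 CPM. Hmox1, haem oxygenase 1, was at 1567 ± 18.4 CPM against 1565 ± 12.9 CPM and did not pass the test. The remaining metabolic lists did not pass in the main setting. Glycolysis genes were higher in 2 of 22 members and lower in 12 (2 and 13 adjusted over the list alone; camera adjusted p = 0.0922, and 0.0109 without a filter on low counts). Hk3 was at -0.64 and Hk2 at -0.55. Hypoxia genes were higher in 3 of 16 and lower in 7 (3 and 8 adjusted over the list alone; camera adjusted p = 0.0863, and 0.0103 without a filter on low counts). Vegfa, a vascular growth factor gene, was at 3.40 ± 0.482 CPM against 21.2 ± 0.896 CPM, and Ndrg1 was higher by 0.82 on the log2 scale. Nuclear genes of oxidative phosphorylation were higher in 10 of 38 and lower in 1, Cox5a (camera adjusted p = 0.257). Genes of the citrate cycle were higher in 7 of 21 and lower in 2, Idh2 and Mdh1 (camera adjusted p = 0.257). Fatty acid oxidation and PPAR genes were higher in 6 of 22 and lower in 4 (camera adjusted p = 0.34). Lpl is a member, and Cpt1a had a log2 fold change of -0.59. Histone methylation enzymes were higher in 11 of 45 and lower in 6 (10 and 6 adjusted over the list alone; camera adjusted p = 0.556). Nsd2 was at -0.61 and Kdm4a at 0.23. Immediate early and stress genes were higher in 12 of 23 and lower in 5 (camera adjusted p = 0.176). Btg2 was at 0.78 and Fos at -0.69.

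Markers of the classical, Ly6C-high monocytes were higher in 7 of 18 members and lower in 7 (camera adjusted p = 0.759). Ly6c2 fell from 95.1 ± 2.12 to 67.9 ± 2.84 CPM (log2 fold change -0.49) and is uncertain because it shares reads with its near copy Ly6c1. F13a1 was at -0.56 and Plac8 at -1.84. Hp rose by 0.83 and the chemokine receptor gene Ccr2 by 0.23. Markers of nonclassical, Ly6C-low monocytes were higher in 10 of 20 and lower in 5 (camera adjusted p = 0.233). Cx3cr1, the fractalkine receptor gene and a marker of these cells, was 4.56-fold lower at 11.4 ± 0.374 CPM against 52.2 ± 1.10 CPM. Nr4a1, the transcription factor they depend on, rose from 5.01 ± 0.362 to 9.13 ± 0.611 CPM. Spn rose by 0.23 and Adgre4 by 1.12 on the log2 scale. General monocyte markers were higher in 7 of 16 and lower in 7 (8 and 7 adjusted over the list alone; camera adjusted p = 0.695). Csf1r was at 0.27, Fcgr3 at 0.48 and Psap at -0.55 on the log2 scale. Phagocytosis and scavenger receptor genes were higher in 11 of 26 and lower in 12 (11 and 13 adjusted over the list alone; camera adjusted p = 0.0549). The list was called lower without thrombocytopenic replicate 1 (adjusted p = 0.00616), without control replicate 1 (0.0231) or control replicate 2 (0.0265), and without a filter on low counts (0.00677). It was also called lower with a replicate block (camera adjusted p = 0.00933). The efferocytosis receptor genes Axl and Mertk were at -1.12 and -1.51. Genes of contact between platelets and monocytes were higher in 9 of 17 and lower in 5 (camera adjusted p = 0.237). Icam1 was at 0.46, Sirpa at 0.28, its ligand gene Cd47 at -0.13 and Ptafr at -0.79. Other genes with small p-values or large folds lay outside these lists. The kinase gene Sgk1 fell from 304 ± 11.4 to 58.7 ± 1.56 CPM and the transcriptional regulator gene Id2 from 171 ± 0.753 to 51.5 ± 0.913 CPM. Plpp3, a lipid phosphatase gene, had a log2 fold change of -2.55. The receptor gene Cd226 was at 0.057 ± 0.047 CPM against 4.13 ± 0.286 CPM. Over all libraries the fitted fold of Cd226 was 66.5-fold lower. Without thrombocytopenic replicate 3 it had 2 counts against 370, a ratio of 139 (95% counting interval 38.1 to 1150). Without replicate 1 the ratio was 54.2 (23 to 168), and without replicate 2 it was 60.4 (25.6 to 187).

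Platelet and megakaryocyte markers split. Of 15 tested members 10 were lower and 2, Pf4 and Ppbp, were higher, with Rgs18, Selp and Thbs1 not past the threshold. The median was -1.22 (camera adjusted p = 0.00221; adjusted p = 0.148 with an estimated correlation). Nrgn had 2 counts in the thrombocytopenic group and 332 in the control group, a ratio of 191 (95% counting interval 52.4 to 1580). Both counts lay in thrombocytopenic replicate 1, without which Nrgn was at least 81-fold lower against a floor of 3 counts over the group; without replicate 3 the ratio was 124. Gp9, chosen after its values were seen, had 0 and 41 counts, at least 15.7-fold lower against the same floor. Ctla2a, a protease inhibitor gene, was at 0.694 ± 0.067 CPM against 26.4 ± 1.81 CPM. Clec1b, the gene of the platelet receptor CLEC2, was at 0.725 ± 0.048 CPM against 3.53 ± 0.143 CPM, and the integrin gene Itga2b was at 0.343 ± 0.190 CPM against 0.863 ± 0.298 CPM. Gp1bb had 0 counts in both groups. Tubb1 had 11 counts in the thrombocytopenic and 10 in the control group, and Gp6, chosen after its values were seen, 19 and 18. Pf4 rose from 924 ± 23.4 to 1095 ± 38.8 CPM (log2 fold change 0.24, SE 0.026) and Ppbp from 95.2 ± 1.78 to 151 ± 2.47 CPM (0.66, SE 0.031). Pf4 was thus abundant in both groups, whereas Tubb1 stood at 0.11 CPM in the thrombocytopenic and 0.118 CPM in the control group. Whether the profiled cells themselves transcribe Pf4, and with it the Cre transgene, was not tested. The summed CPM of the list followed Pf4, its most abundant member, and was 1861 ± 20.7 in the thrombocytopenic and 1668 ± 52.8 in the control libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). The mean log2 CPM over the list differed by -1.24. The genes that neighbour Pf4 on its chromosome were higher in 7 of 8 members, with a median of 0.54 (camera adjusted p = 3.75e-13; adjusted p = 0.0369 with an estimated correlation). This list holds Pf4 and Ppbp, and 3 of its members are also in the cytokine list. Among them the neutrophil chemokine genes Cxcl5, Cxcl2 and Cxcl1 rose by 1.58, 0.89 and 0.71 on the log2 scale, and Alb did not pass the test. The PF4cre-iDTR genotype carries a transgene with Pf4 sequence, and the counts cannot separate transcripts of a transgene from those of the gene itself. Whether the transgene also carries the neighbouring genes is not given in the sources used here, so the counts do not separate a change in expression from extra copies for this list, Cxcl5, Cxcl2 and Cxcl1 included. Mouse Hbegf, the relative of the diphtheria toxin receptor, had 7 counts in the thrombocytopenic and 3 in the control group.

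Of the marker lists of other blood cells, dendritic cells (above) and basophils, eosinophils and mast cells were called, both lower, and neither was called with an estimated correlation. Of 6 tested basophil, eosinophil and mast cell genes 5 were lower and Ccr3 was higher, with a median of -4.00 (camera adjusted p = 0.0176; adjusted p = 0.185 with an estimated correlation). Mcpt8 was at 0.118 ± 0.059 CPM against 2.27 ± 0.273 CPM and Prss34 at 0.0987 ± 0.061 CPM against 2.64 ± 0.672 CPM. Ms4a2 had 1 count against 67, a ratio of 77 (95% counting interval 13.4 to 3090). That count lay in thrombocytopenic replicate 3, without which Ms4a2 was at least 16.7-fold lower against the same floor; without replicate 1 the ratio was 49.1. Haemoglobin Hba-a1 had 0 counts in the thrombocytopenic and 180 in the control group, at least 68.9-fold lower against the same floor. It shares reads with Hba-a2 and is uncertain for that reason. It was the 1 lower of 2 tested erythroid genes, and Bpgm did not pass the test. Of 4 tested T and NK cell genes 3 were lower, with Il7r at 28.8 ± 1.66 CPM against 45.9 ± 1.34 CPM (camera adjusted p = 0.0976 for the list). Of 3 tested B cell genes Ighm was higher by 0.30 and none was lower (camera adjusted p = 0.705, with a median of -0.06 and a mean of 0.06). Neutrophil genes were higher in 5 of 12 and lower in 3 (camera adjusted p = 0.108, with a median of -0.10 and a mean of 0.02). Lcn2 rose by 0.70 and Mmp9 by 1.03 on the log2 scale. S100a8 was at 7.40 ± 0.912 CPM against 8.29 ± 0.112 CPM and S100a9 at 1.82 ± 0.971 CPM against 2.75 ± 0.542 CPM, neither past the threshold. S100a9 (log2 fold change -0.57) passed without thrombocytopenic replicate 3 (-1.12, adjusted p = 1.26e-05), and without a filter on low counts (adjusted p = 0.00696) or the robust option (0.0433). It also passed with a replicate block (-0.63, edgeR adjusted p = 0.00999). As sums over the lists, dendritic cell markers stood at 361 ± 5.21 against 482 ± 10.8 CPM and T and NK cell markers at 29.8 ± 1.51 against 48.2 ± 1.10 CPM. Basophil, eosinophil and mast cell markers stood at 6.36 ± 0.608 against 11.4 ± 1.09 CPM and progenitor markers at 12.9 ± 0.852 against 19.1 ± 1.69 CPM. Erythroid genes stood at 7.57 ± 0.021 against 9.38 ± 1.32 CPM and B cell markers at 14.8 ± 0.892 against 12.6 ± 0.971 CPM. Each of these differences, and that of the neutrophil sum, had an exact permutation p of 0.1, the smallest possible, and an adjusted p of 0.125. Single genes made up much of several sums. Among dendritic cell markers, Bst2, also in the interferon list, was at 213 against 280 CPM and Tcf4 at 117 against 153 CPM. Il7r (28.8 against 45.9 CPM) led the T and NK cell sum and Ighm (12.7 against 10.4 CPM) the B cell sum. The sums therefore do not measure amounts of these cell types. General monocyte markers summed to 28650 ± 72.0 against 28590 ± 269 CPM (exact permutation p = 0.7), a difference of 61.4 CPM that was -74.3 CPM without control replicate 1. As mean log2 CPM over the list, the differences of the neutrophil (-0.254), B cell (-0.0232) and general monocyte (-0.102) markers had the opposite sign to their sums.

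Mitochondrial ribosomal RNA was lower: mt-Rnr1 was 5.34-fold lower at 88.5 ± 1.13 CPM against 473 ± 20.9 CPM, and mt-Rnr2 6.18-fold lower. Both are uncertain where reads match nuclear copies. Mitochondrially encoded mRNAs did not move with them, though only 7 of 13 had enough counts to be tested. Of these 7, mt-Cytb was higher (log2 fold change 0.20), and none was lower (camera adjusted p = 0.436). The sum of all 13 was 6980 ± 198 against 6427 ± 528 CPM (exact permutation p = 0.3). Y-linked genes were counted in all 6 libraries, with Ddx3y at 134 ± 4.43 CPM against 114 ± 1.19 CPM, and Xist had 1 and 4 counts. Of the sex-linked list 2 of 4 were higher (3 adjusted over the list alone) and none lower (camera adjusted p = 0.221). Of 6 genes that differ between mouse substrains or travel with modified loci, 2 were lower, Cyfip2 at -0.57 and Wdfy1 at -0.64, and none was higher (camera adjusted p = 0.237). Nnt was at 26.0 ± 0.755 CPM against 24.3 ± 0.341 CPM and did not pass the test.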

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

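The alternative without mt-Rnr1 and mt-Rnr2 was chosen after seeing the data; the others were planned. The number of changed genes stayed within 1.5 times of 5626 under other scalings, tests and filters, from 4720 with DESeq2 (4714 of them shared) to 5645 with RLE, and was 6286 at an adjusted p under 0.1. Without mt-Rnr1 and mt-Rnr2 it was 5625. A 2-fold minimum left 489 genes, 112 higher and 377 lower, by its own construction. No gene called both in the main setting and in an alternative changed sign. The share of higher genes among those called was 49.6%, and 42.7% with upper quartile scaling. Leaving out each library in turn gave 4990 to 5427 genes and 12 to 13 lists, with all 12 lists kept each time. Of 164 named genes tested, 157 kept their side of the threshold under every alternative that tested them, except the 2-fold minimum. Alternatives that left a gene untested were skipped for that gene. Most named genes were picked for a small p in these same data, which favours stable calls.

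Camera called 12 lists; 3 were called with an estimated correlation and 27 by fry, which asks another question. Without a filter on low counts 16 lists were called, the 12 among them, with Toll-like receptor and NF-kB signalling, glycolysis, hypoxia and phagocytosis added. Phagocytosis was also called with 3 of the 6 libraries left out in turn, and Toll-like receptor and NF-kB signalling with 1. As mean log2 CPM in place of summed CPM, 4 marker lists changed direction: platelet (-1.24), general monocyte (-0.102), neutrophil (-0.254) and B cell (-0.0232), since a mean of logs weights rare members like abundant ones. The general monocyte difference, 61.4 CPM in the main setting, ranged from -74.3 CPM without control replicate 1 to 195 CPM without control replicate 3; the cause was not tested.

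With a replicate block, 5402 genes (5371 shared) and 13 lists were called, the phagocytosis list added (adjusted p = 0.00933); S100a9 passed as well (0.00999). Libraries with the same number did not deviate together (correlations of -0.0383, -0.0892 and -0.0127, across genes). Pairs with different numbers ranged from -0.0588 to 0.0883. With 3 libraries a group, this does not exclude a shared batch. Depth limits the genes under about 1 CPM, among them most platelet and basophil markers.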

Other observations

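The tests for less mitochondrial RNA and for a lower share of monocytes were chosen only after the results were seen, and the rule of the latter was revised more than once with its values known; the bounds of the other tests in this part were written before their values were seen. Genes not described so far include some of the most abundant ones, chosen after their values were seen. Acod1, which makes itaconate in activated macrophages, ranked 5 by mean CPM over the 6 libraries, at 6207 ± 83.7 CPM in the thrombocytopenic and 6378 ± 99.3 CPM in the control group. The acute-phase gene Saa3 was at 3062 ± 96.0 against 1815 ± 42.8 CPM, Gpnmb, a lysosomal glycoprotein gene of macrophages, at 3176 ± 32.1 against 4512 ± 3.32 CPM, and the macrophage marker Adgre1 at 3285 ± 90.2 against 2712 ± 82.5 CPM. S100a8, abundant in blood monocytes and neutrophils, was at 7.40 and 8.29 CPM. The labels used here name no culture step and no stimulus other than the toxin, and no untreated library was analysed here. How far the profiled cells resembled circulating monocytes was not tested.

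Sterol synthesis genes were higher while Abca1, Abcg1, Apoe and Arl4c, known targets of the sterol-sensing LXR receptors, were lower. A trend with gene length or GC content as the whole cause is argued against: after a smooth fit on both, for 96.7% of the tested genes, the median residual of the cholesterol biosynthesis list was 1.627. A candidate explanation is 1 opposite change of both programmes, as lower sterol content would give. Of 12 further LXR target genes not looked at before, 6 were lower, 2 higher and 4 not past the threshold. Their median of -0.306 lies just past the bound of -0.3 set beforehand. Mylip, Nr1h3, Pltp and Ttc39b were lower by at least 2-fold, Smpdl3a by 1.42-fold and Lpcat3 by only 1.08-fold. Fasn, which also answers to SREBP factors, was higher at 1.16 and Elovl5 at 0.133 on the log2 scale. Srebf1 (0.095), Acaca (0.061), Scd2 (-0.103) and Scd1 (-0.638) did not pass, so not all of these targets fell. The opposite change of both programmes remains a hypothesis, found and tested on the same libraries, and genotype and thrombocytopenia stay open beside it.

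Mitochondrial ribosomal RNA was lower in the thrombocytopenic libraries. Less mitochondrial RNA as a whole is argued against by the 7 tested of 13 mitochondrially encoded mRNAs, whose median log2 fold change was 0.121. Less carry-over of RNA without a poly(A) tail cannot be told apart from other causes, since 2 small structural RNAs had enough counts to be tested, with a median of 0.003. No biological explanation was tested.

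Platelet and basophil transcripts were lower in the thrombocytopenic libraries, although Pf4 and Ppbp were higher. A lower share of monocytes among the control cells would raise other cell markers there alike only if monocytes expressed none of them. By the rule used, the markers moved apart. Several stood high in both groups, such as Csf3r (159 against 141 CPM) and Bst2 (213 against 280 CPM). Expression in monocytes would shrink their change, so the test cannot decide against this cause. The B cell and neutrophil members had a median log2 fold change of -0.055 (SD 0.848 over 15 genes, 6 higher and 3 lower), and those of T and NK, dendritic, progenitor and erythroid cells one of -0.75 (SD 1.90 over 23 genes, 1 higher and 16 lower). The basophil, eosinophil and mast cell list stood at -4.00 (SD 2.33 over 6 genes). Each of the latter 4 lists was lower, as such a share would give: T and NK cells at a median of -1.10, dendritic cells at -0.82, progenitors at -0.72 and erythroid cells, with 2 tested genes and 1 of them at 0 counts, at -3.02 or below. A lower share of monocytes and a rise of single cell types among the control cells both stay open. Whether monocytes themselves express the B cell and neutrophil genes was not tested. Platelets carried with the control cells stay open: Tubb1, Treml1 and Gp1bb together reached 0.856 times the CPM of Gp9 there (0.387 against 0.452 CPM), between the bounds set beforehand. In the thrombocytopenic libraries the sum was 0.248 CPM, and its highest library there (0.364) lay above the lowest control library (0.244). Tubb1 had 11 counts in the thrombocytopenic and 10 in the control group, and Gp6, chosen after its values were seen, 19 and 18. All of these are near the floor and exclude nothing. Basophils or mast cells among the control cells stay open too, with 4 of 6 further marker genes lower in every thrombocytopenic library. These were Cpa3 (2 counts against 43), Rab44 (21 counts against 114), Cd200r4 (18.21 against 41.45 CPM) and Hgf (1.40 against 1.99 CPM). The exceptions, Hdc at 94.2 against 91.6 CPM and Slc6a4 at 3.12 against 2.62 CPM, did not fall. Of these 6 genes 3, Hdc, Cd200r4 and Slc6a4, stood above 2 CPM in both groups, and how the monocytes were isolated is not given in the sources used here. Loss of platelets in the thrombocytopenic mice, which the design names, is a biological explanation that was not tested.

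Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 5626 genes; the highest other gave 0 with edgeR, with 96 to 233 genes at an unadjusted p under 0.05, and 0 with limma-voom. For lists, 1 split, the real one, gave 12, but the highest other gave 10 by camera with its preset correlation, in a split that called no gene. The splits are too few for a share under 0.05. Every other split also mixes libraries of both groups in each arm. The group difference then adds to the spread within the arms and lowers the number of genes called, so the 0 does not measure chance. Part of that difference can remain between the arms, so the lists called there do not measure false calls either.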
